A study of Mus musculus with 25 samples.

How the data were processed

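The series measured polyA RNA by bulk sequencing in 25 libraries of macrophages sorted from mouse lung. The mice were mixed bone marrow chimeras, that is, hosts rebuilt with marrow of 2 donors, so that knockout and WT cells develop in one animal. In the IL9R chimeras the donors were Il9r knockout (KO) and congenic WT mice. In the ARG1 chimeras they were mice labelled ARG1 CKO (conditional knockout) and WT mice. The labels give a B16 tumor (a mouse melanoma line), the QIAGEN micro kit and the SMART-seq v4 and Nextera XT library protocols. Tumor libraries held CD11c- or CD11c+ interstitial macrophages (IM), and naive libraries held total macrophages. All 25 libraries carried 1 batch label.

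The deposited table gives raw read counts per gene, 1 column per library, for 13482 genes. Per the submitters' processing notes, reads were checked with FastQC 0.11.5, aligned to mm10 with STAR 2.7.10a and counted with featureCounts of Subread 2.0.3. The annotation, the strand setting, the handling of reads that match several places and the filter behind the 13482 genes were not given in the sources used here. In the table each gene had at least 49 reads in total and at least 10 reads in at least 2 libraries. Genes were identified by symbol alone. The table's identifier column named the same gene as its symbol column in 262 of 11999 comparable entries (2.18%), checked against GENCODE vM21. The counts followed the symbols: Itgax, the gene of CD11c, averaged 338 CPM (library totals scaled to 1e6 counts, here without TMM) in CD11c+ and 19.4 in CD11c- WT tumor libraries by symbol. The entry found by its identifier gave 477 and 536. Positions were looked up by symbol in GENCODE vM21 (mm10, GRCm38) for 12971 genes (96.2%). Where genes of a family share sequence, as Dynlt1b, Lyz1 and Lyz2, the H2 genes, Pydc3 and Ear2 do, reads could have been split or lost in counting.

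Library totals ran from 32308968 to 56904167 counts, with 12113 to 13209 genes detected (median 12518). A gene without a read in a library was given a floor of 3 counts per library for lower bounds on folds. The protocol names no molecular identifiers, so these floors cover counting error only.

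Groups came from the labels: 8 tumor groups (2 chimera kinds, 2 IM subsets, 2 genotypes) of 2 or 3 libraries and 4 naive groups of 1 library. Nothing states that the libraries came from separate animals, so p-values measure only the spread between these samples. Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, robust quasi-likelihood fit, two-sided tests, Benjamini-Hochberg adjusted p under 0.05). The 21 tumor libraries were fitted together with a term per group, which left 13434 genes (48 removed) and 13 residual degrees of freedom. The biological coefficient of variation was 49.2%. Tumor and naive cells were compared within the 12 WT libraries, with population and chimera kind as terms, over 13170 genes (312 removed) with 8 residual degrees of freedom. These fits were used for 12 comparisons. The naive knockout and WT libraries were compared as log2 ratios without a test. Levels are mean CPM with TMM scaling, and log2 CPM used a prior count of 2. Log2 fold changes are given with their standard error (SE).

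The tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named Il9r, Arg1, Itgax and Ptprc (CD45, the congenic marker) in each comparison. It added the 8 highest and 8 lowest log2 fold changes among called genes with a mean of at least 5 CPM in the higher group and libraries that do not overlap. It further added up to 4 called genes per list by smallest adjusted p, and all calls where there were 5 or fewer. Called means an adjusted p under 0.05. Genes with only a model name were left out except in those small sets of calls. Values of some genes that the rule names are not reported here. There were 29 lists, 14 of them markers of cell types. One list of 8 blood genes had too few measured members, so 28 were tested. Lists were tested with camera (limma 3.58.1) with a preset correlation between genes of 0.01, with camera with an estimated correlation, and with fry, each adjusted over the lists of a comparison. Camera compares a list with all other genes. Fry tests whether the genes of a list move, on balance, one way, and does not compare them with other genes. Counts of called members are given over all genes tested and adjusted over the list alone.

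The labels number the libraries within each group but name no animal. Over 8019 genes (mean log2 CPM of at least 3), deviations from the group means of WT and knockout libraries with the same number correlated at 0.25 to 0.47 in the IL9R chimeras and at 0.22 to 0.4 in the CD11c- libraries of the ARG1 chimeras, so the numbers were taken to pair these. The correlations were -0.08 and -0.18 in the CD11c+ libraries of the ARG1 chimeras, where the numbers were not taken as pairs. The labels also count the libraries from 1 to 28 without 7, 10 and 26, so that CKO libraries 1 and 2 of this group carry 27 and 28. They correlated at 0.18 and 0.07 with WT libraries 2 and 3, so which libraries belong together there is not known. A block for all label numbers was planned, and a block that leaves these CD11c+ libraries untied was added.

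The alternatives were the DESeq2 1.42.0 Wald test, limma voom with sample weights, DESeq2 size factors, no filter, a block for the label number, fits of only the groups contrasted, all 25 libraries for the naive comparisons, and leaving out each library in turn. Chosen after seeing the data were leaving out the IL9R chimera libraries numbered 3 (genes and lists), the block that ties only paired libraries, the correlation of genotype effects without chromosome 1 genes, and a test of the difference of the 2 genotype effects. So were exchanges of Arg1 within pairs, permutations that move libraries of one number together, splits that follow the numbers, and all tests of explanations for Ctse and Chil1, for the Il9r reads and for Lyz2 and Lyz1. The pipeline was tested on simulated data. Counts were drawn independently for each library, from a single mean per gene and the dispersions that edgeR estimated. These data hold no pairs by number and no outlying library, and they follow the model of edgeR. For each effect 100 genes were changed 2-fold and 100 changed 4-fold. edgeR found 48% and 71% of these in the averaged Il9r comparison, 48% and 76% in the averaged Arg1 comparison, 46% and 72% between IM subsets, 16% and 57% between CD11c- tumor and naive libraries, and 20% and 56% between CD11c+ tumor and naive libraries. Within CD11c- IM it found 23% and 58% for Il9r and 29% and 71% for Arg1, and within CD11c+ IM 22% and 60% for Il9r and 13% and 63% for Arg1. Of 75 to 135 edgeR calls, 2 to 11 were false. DESeq2 made 22 to 50 false calls of 117 to 183, and voom 0 to 7 of 61 to 124.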

Results

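Gene expression was measured in 25 libraries of lung macrophages from 2 kinds of mixed bone marrow chimera, to find changes inside interstitial macrophages (IM) that depend on IL-9 signaling. In the IL9R chimeras with tumor there were 2 WT and 3 Il9r knockout (KO) libraries of CD11c- IM and 2 WT and 3 KO libraries of CD11c+ IM. In the ARG1 chimeras with tumor there were 3 WT and 3 Arg1 CKO libraries of CD11c- IM and 3 WT and 2 CKO libraries of CD11c+ IM. Each chimera kind had 1 WT and 1 knockout library of naive total macrophages, without replicates. Library totals were 32308968 to 56904167 counts. Over the 1000 most variable genes, the first principal component (30% of the variance) set the CD11c- libraries (10.42 to 54.61) apart from the naive libraries (-72.34 to -51.61). The second (10.6%) set most CD11c+ libraries below the others. CD11c+ library 3 labelled Il9r KO lay apart on the third (-65.31) and within the range of the naive libraries on the first (-52.48). Genes of B16 melanoma cells made up 0.127% of its counts, against 0.00631% to 0.0118% in the WT CD11c+ libraries.

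**Figure D1:**
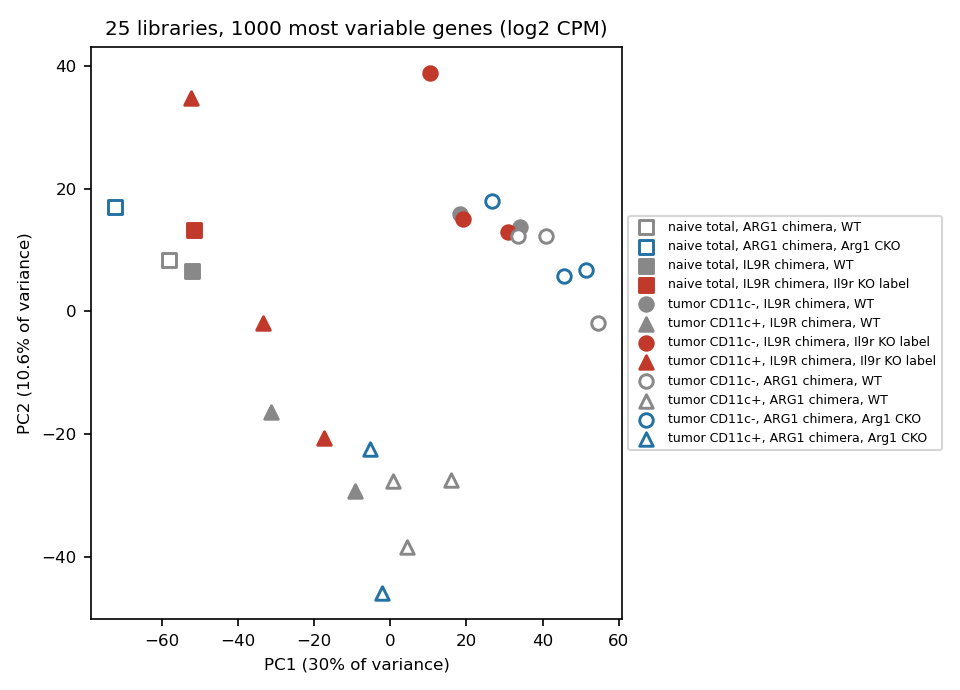
Each point is 1 of the 25 libraries, placed by its first (30% of the variance) and second (10.6%) principal component of log2 CPM over the 1000 most variable genes, with colour and shape for its group. The CD11c- tumor libraries lie at 10.42 to 54.61 on the first component and the naive libraries at -72.34 to -51.61.

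Arg1, which splits arginine into ornithine and urea (chromosome 10, 24915221 to 24927484, mm10), was lower in the Arg1 CKO libraries. In CD11c- IM of the ARG1 chimeras it averaged 2270 CPM (SD 541, n = 3) in CKO and 4810 CPM (SD 1320, n = 3) in WT libraries. In CD11c+ IM it averaged 525 CPM (SD 59.1, n = 2) and 1760 CPM (SD 1000, n = 3), and in neither subset did a CKO library reach a WT library. Over both subsets the log2 fold change was -1.42 (SE 0.40). The difference of mean log2 CPM was -1.34 (exact permutation p = 0.005, the smallest that 200 permutations give). These permutations count each library as independent. In the 3 CD11c- pairs of one number Arg1 was lower in each CKO library (mean log2 difference -1.08). Exchanges within these pairs gave an exact p of 0.25, the smallest possible. Over all genes the edgeR adjusted p of Arg1 was 1. In the IL9R chimeras Arg1 averaged 3070 CPM (SD 1330, n = 3) in CD11c- IM labelled Il9r KO and 3970 CPM (SD 805, n = 2) in WT, and 591 CPM (SD 428, n = 3) and 1070 CPM (SD 7.63, n = 2) in CD11c+ IM. The log2 fold change over both subsets was -0.61 (SE 0.41) and did not pass (edgeR adjusted p = 1). The difference of mean log2 CPM was -0.91 (exact permutation p = 0.17). Arg1 was lower in all 4 KO libraries with a WT library of the same number (mean log2 difference -0.24, exact p = 0.125 with exchanges within these pairs, the smallest possible). These pairs hold label numbers 1 and 2 only, each in both subsets. CD11c- and CD11c+ libraries of one number deviated alike (r 0.28 for both numbers in WT, 0.2 and 0.41 in KO). The exact p counts the 4 pairs as independent and is too small if they are not. With a block where the numbers pair libraries the log2 fold change was -0.20 (adjusted p = 1). The difference in Arg1 did not vary detectably between the subsets (CD11c+ minus CD11c-: -0.47, SE 0.82, for Il9r and -0.65, SE 0.78, for Arg1).

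Il9r, the receptor chain that binds IL-9 (chromosome 11, 32187541 to 32200279), had 0 reads in all 12 WT libraries and had reads in all 7 libraries labelled Il9r KO. In CD11c- IM these held 179 to 562 reads (7.42 CPM, SD 4.45, n = 3), at least 104-fold above the WT floor of 3 counts per library. In CD11c+ IM they held 83 to 168 reads (2.98 CPM, SD 1.2, n = 3), at least 38.3-fold above it, and the naive library held 163. The difference over both subsets had an exact permutation p of 0.01, the smallest that 100 permutations give, with each library counted as independent. Its edgeR adjusted p was 0.121. Il9r was called with a block for all label numbers, but not with a block that ties only paired libraries. In the ARG1 chimeras 1 CD11c+ CKO library held 61 reads, and 1 CD11c- CKO library and the naive CKO library held 5 each. Counts per gene do not show which exons the reads cover, and the labels do not describe the Il9r allele.

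**Figure D2:**
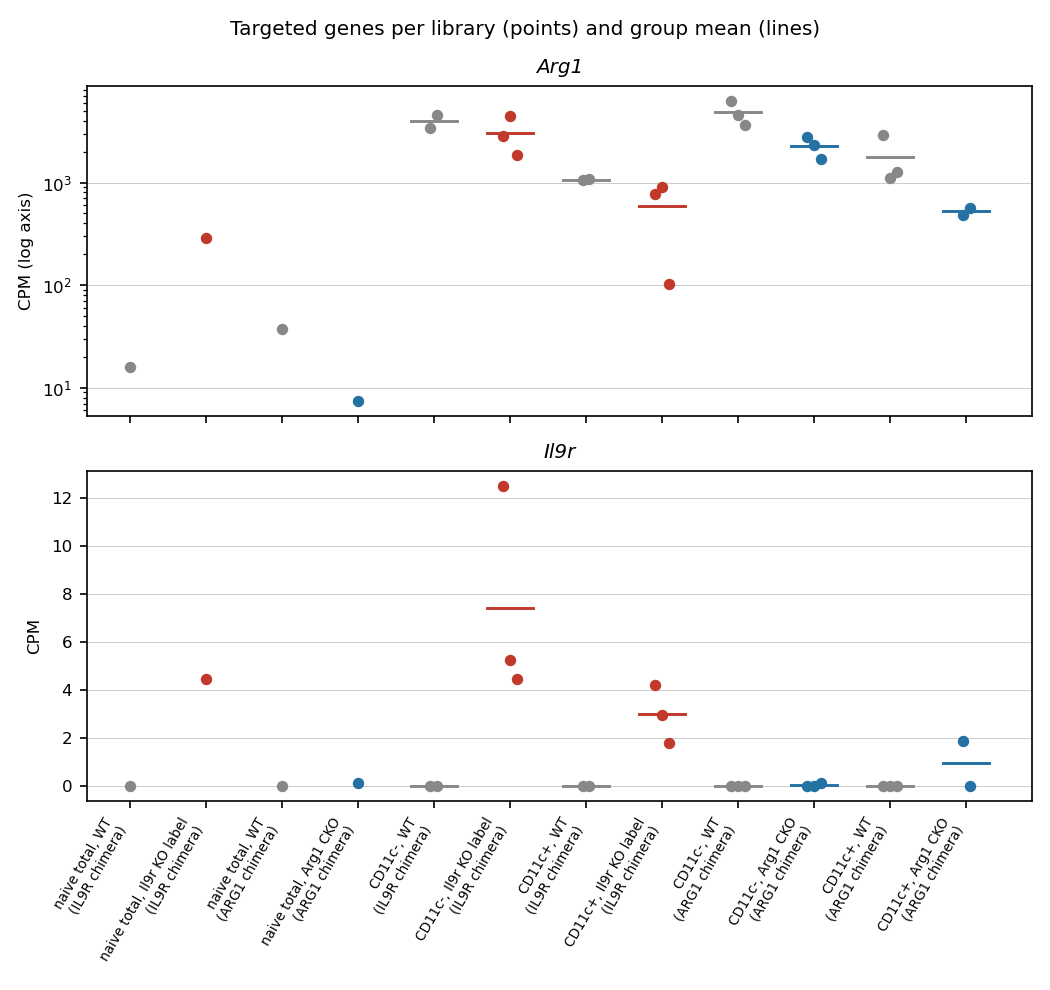
Points are single libraries and lines are group means, with Arg1 CPM on a log axis and Il9r CPM on a linear axis for the 12 groups. Arg1 averages 4810 CPM in WT and 2270 CPM in CKO CD11c- IM of the ARG1 chimeras, and Il9r is at 0 in all WT libraries and above 0 in all libraries labelled Il9r KO.

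Cells labelled Il9r KO were compared with WT cells of the same chimeras. Since Il9r reads were found in the KO and not in the WT libraries, the values below are differences between the labelled groups and do not show what the presence of the receptor changes. Ctse, an intracellular aspartic protease, fell over both subsets from 47.9 to 6.63 CPM (log2 fold change -2.85, SE 0.27, adjusted p = 8.44e-06), and Chil1, a chitinase-like secreted protein, from 75 to 10.9 CPM (-2.94, SE 0.43, adjusted p = 0.00562). Dynlt1b, a dynein light chain of a family of near-identical copies, fell from 6.91 to 0.259 CPM (-4.70, SE 0.27, adjusted p = 5.14e-09). Gdf3, a growth factor of the TGF-beta family, fell from 214 to 71.1 CPM (-1.61, SE 0.24, adjusted p = 0.00596). Wdfy1, an endosomal adaptor protein, rose from 10.7 to 76.9 CPM (2.86, SE 0.24, adjusted p = 1.14e-06) and Fn3krp, a kinase that acts on glycated proteins, from 0.618 to 7.76 CPM (3.80, SE 0.66, adjusted p = 0.0279). These 6 and 1 lower gene with only a model name were the 7 calls, of 562 genes at an unadjusted p under 0.05 (chance alone gives 672).

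Within CD11c- IM the 3 calls were Wdfy1 (2.81, SE 0.33, adjusted p = 0.000408), Dynlt1b (-5.31, SE 0.40, adjusted p = 4.41e-07) and Ctse (-2.89, SE 0.38, adjusted p = 0.00165). Within CD11c+ IM the same 3 genes were called (Wdfy1 2.90, Dynlt1b -4.10, Ctse -2.82), with Pydc3, a gene of the pyrin family, at 2.97 against 12.4 CPM (-2.06, SE 0.34, adjusted p = 0.03). By edgeR 836 genes had an unadjusted p under 0.05 in CD11c- IM and 380 in CD11c+ IM (chance alone gives 672). This fit leaves out the pairs by number, so few calls do not show that little changed. For a difference that varied between the subsets edgeR called 0 genes (740 at an unadjusted p under 0.05), voom 0 and DESeq2 7, and edgeR called 12 without CD11c- WT library 2. DESeq2 called 53 genes over both subsets, 29 in CD11c- and 34 in CD11c+ IM, and edgeR fitted on the contrasted groups alone called 0 in either subset (550 and 307 genes at an unadjusted p under 0.05). Within CD11c- IM edgeR called 51 genes without CD11c- WT library 2, and 5 with a block where the numbers pair libraries. Over both subsets it called 4 without CD11c- WT library 1 or 2 and 3 without CD11c+ WT library 1. Chil1 lost its call without CD11c- WT library 1 (adjusted p = 0.0742) or CD11c+ WT library 1 (0.051), and Gdf3 without CD11c- WT library 2 (0.0589) or CD11c+ WT library 1 (0.0634), and both lost it in the fit of the contrasted groups alone (0.214 and 0.419). Fn3krp lost it under 12 of 18 alternatives (adjusted p 0.0508 to 0.441), among them each WT library left out in turn (0.361 and 0.135 for CD11c-, 0.441 and 0.0762 for CD11c+), KO libraries 2 and 3 of CD11c- (0.0843, 0.0972) and of CD11c+ IM (0.0508, 0.0819). Pydc3 lost it under 9 of 13, among them without CD11c+ WT library 1 (adjusted p = 1) and each KO library (0.134, 0.0666, 0.205). Itgax (log2 fold change 0.18 over both subsets) and Ptprc (-0.14) were not called.

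Glycolysis and hypoxia genes lay lower on average in the libraries labelled Il9r KO: all 27 measured members had a negative log2 fold change over both subsets (median -0.36). None was called over all genes and 1 was adjusted over the list alone (camera adjusted p = 2.35e-11, and 0.388 with an estimated correlation). Interferon response genes were lower as a set too (31 of 35 negative, median -0.30, adjusted p = 2.56e-06, and 0.41 with an estimated correlation), and alveolar macrophage markers higher (20 of 21 positive, median 0.56, adjusted p = 0.000189, and 0.41 with an estimated correlation). With fry the adjusted p was 0.445 for glycolysis, 0.544 for interferon and 0.462 for alveolar markers. The arginine and polyamine list, which holds Arg1, was lower with 19 of 24 members negative (median -0.11, adjusted p = 0.00901, and 0.388 with an estimated correlation). The list of the IL-9 receptor and its JAK-STAT feedback genes did not pass (adjusted p = 0.477). Markers of B16 melanoma were higher in the same comparison (14 of 14 positive, adjusted p = 3.71e-06, and 0.388 with an estimated correlation). So were those of B and plasma cells (9 of 9, 1.25e-05 and 0.388) and T and NK cells (15 of 15, 0.013 and 0.508). Reads of Cd3d, Cd3e and Cd3g together numbered 80 (CD11c-) and 455 (CD11c+) in the KO libraries numbered 3. The other tumor KO libraries held 0 to 7 and the tumor WT libraries of these chimeras 2 to 33. T cell reads were thus not higher in KO libraries in general. Values of these list tests without the libraries numbered 3 are not given here. Of the 28 lists tested, 14 passed camera with the preset correlation, and 0 with an estimated correlation or fry. CD11c+ library 3 labelled Il9r KO, the one with 0.127% of counts from B16 genes, had 102 CPM of Arg1, against 774.8 and 895.5 CPM in libraries 1 and 2 of its group. It lay at -52.48 on the first principal component, within the range of the naive libraries (-72.34 to -51.61). How far these list results rest on this 1 library cannot be told from the values given.

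In the ARG1 chimeras Arg1 CKO and WT cells were compared in the same way. Ctse and Chil1 were lower in the CKO libraries here too, Ctse at 3.9 against 30.6 CPM (log2 fold change -2.95, SE 0.29, adjusted p = 3.81e-05) and Chil1 at 5.72 against 42.6 CPM (-3.01, SE 0.46, adjusted p = 0.00744). Lyz2, the lysozyme of macrophages, fell from 21500 to 8130 CPM (-1.44, SE 0.22, adjusted p = 0.00744), while its neighbour and paralog Lyz1 rose from 59.2 to 590 CPM (3.16, SE 0.42, adjusted p = 0.00279). Pwp2, which acts in ribosome assembly, fell from 22.6 to 8.59 CPM (-1.44, SE 0.17, adjusted p = 0.000513). These were the 5 calls over both subsets, of 519 genes at an unadjusted p under 0.05. In CD11c- IM alone Ctse was the 1 call (-2.79, SE 0.37, adjusted p = 0.00404), and 4 were called with a block where the numbers pair libraries. By edgeR 193 genes had an unadjusted p under 0.05 in CD11c- IM and 779 in CD11c+ IM (chance alone gives 672). The main fit leaves out the pairs by number, which can hide differences, so few calls do not show that little changed. In CD11c+ IM 6 genes were called, among them Hal, the enzyme that removes ammonia from histidine, at 5.98 against 0.0664 CPM (6.26, SE 1.05, adjusted p = 0.0297), Lyz1 (3.60, SE 0.62, adjusted p = 0.0458), Ctse (-3.12, SE 0.44, adjusted p = 0.0058) and Pwp2 (-1.89, SE 0.27, adjusted p = 0.0058).

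Single libraries decided many of these calls. Without CD11c+ CKO library 1 the calls over both subsets fell to 3 and Chil1 and Lyz2 had an adjusted p of 0.191 each. Without CD11c+ CKO library 2 they had 0.108 and 0.081. Without CD11c+ WT library 3 the calls over both subsets numbered 8. In CD11c- IM Ctse lost its call without CKO library 1 (adjusted p = 0.0871), which left 0 calls. In CD11c+ IM 3 calls were left without WT library 2, 1 without CKO library 1 and 2 without CKO library 2. Ctse (0.129 and 0.102) and Pwp2 (0.218 and 0.0612) lost theirs without CKO library 1 or 2, Hal (0.191, 0.152, 0.133, 0.0612) without WT library 1 or 2 or CKO library 1 or 2, and Lyz1 without any 1 of the 5 libraries (0.0979 to 0.456). DESeq2 called 25 genes over both subsets, 10 in CD11c- and 44 in CD11c+ IM, and edgeR fitted on the contrasted groups alone 0 in CD11c- (258 at an unadjusted p under 0.05) and 2 in CD11c+ IM. For a difference that varied between the subsets edgeR called 0 genes (519 at an unadjusted p under 0.05), voom 0 and DESeq2 18, and edgeR called 1 without CD11c+ CKO library 1 or 2. Alveolar macrophage markers were higher over both subsets (18 of 21 positive, camera adjusted p = 0.00172), glycolysis and hypoxia genes lower (22 of 27 negative, 0.021) and B16 markers higher (12 of 14 positive, 0.00665), each with an adjusted p of 0.928 with an estimated correlation and 0.959 with fry. The arginine and polyamine list did not pass (adjusted p = 0.214). Itgax (log2 fold change 0.31) and Ptprc (0.16) were not called.

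**Figure D3:**
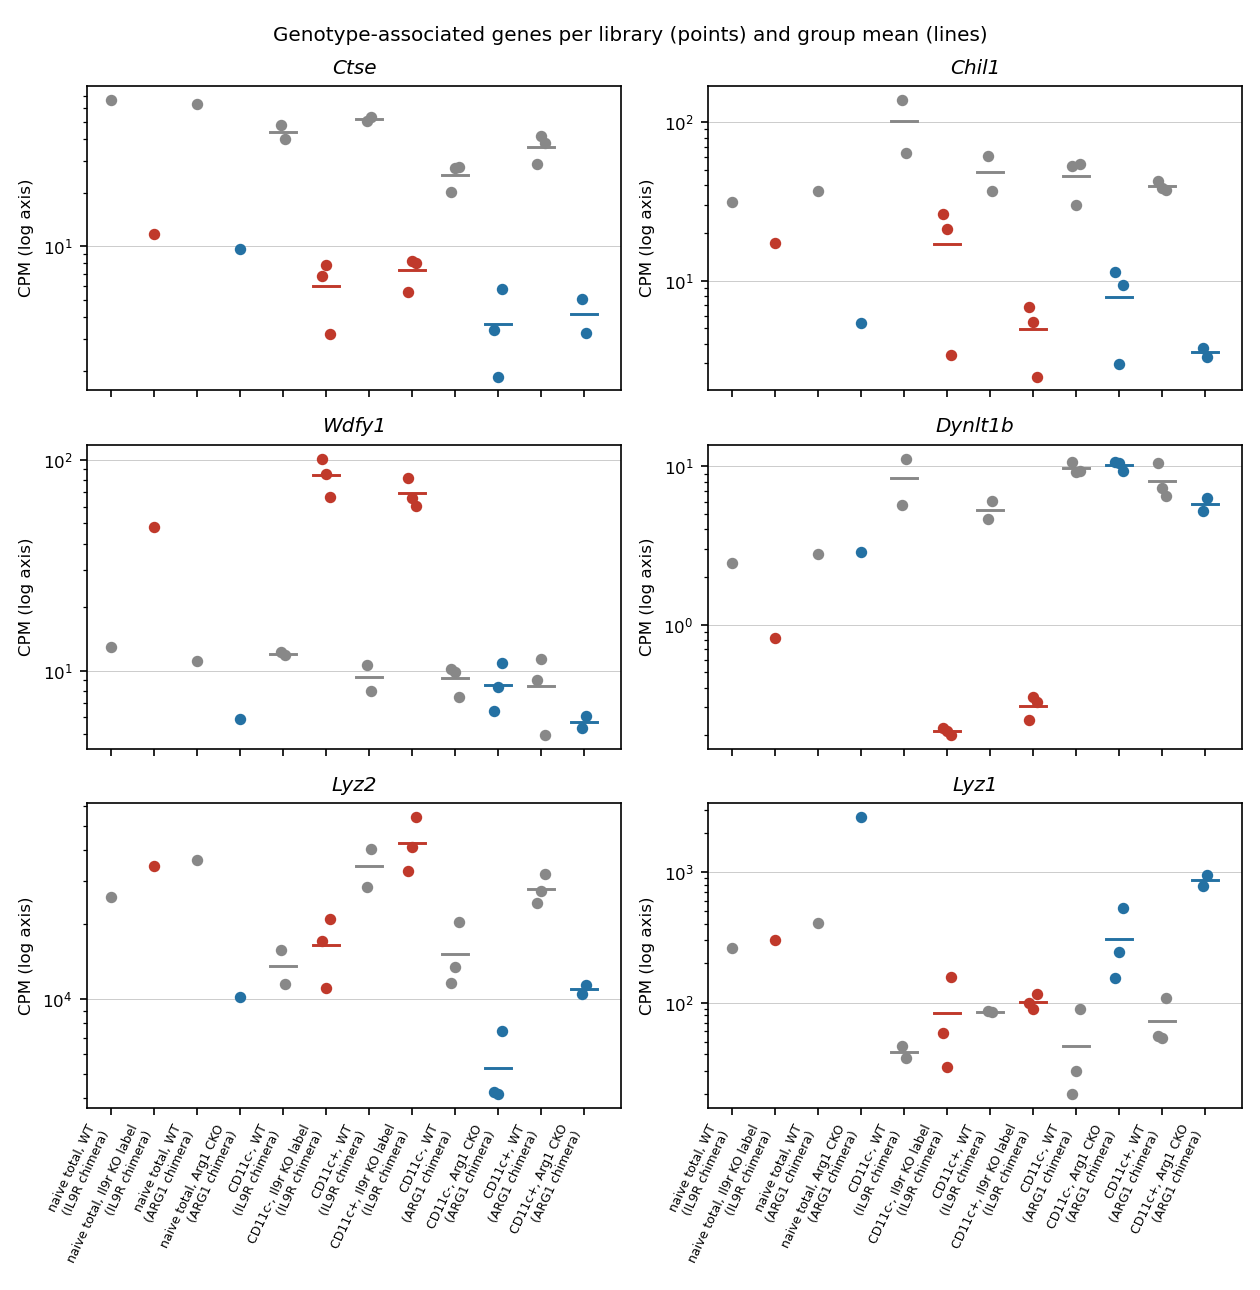
Points are single libraries and lines are group means in CPM on a log axis for Ctse, Chil1, Wdfy1, Dynlt1b, Lyz2 and Lyz1 in the 12 groups. Ctse averages 6.63 CPM in cells labelled Il9r KO and 47.9 CPM in WT cells of the IL9R chimeras, and 3.9 and 30.6 CPM in CKO and WT cells of the ARG1 chimeras.

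The differences between knockout and WT libraries of both chimera kinds were set side by side to ask how much they share. Ctse (chromosome 1, 131638306 to 131675505) and Chil1 (chromosome 1, 134182176 to 134190181) were the 2 genes lower in both, where chance gives 0.00149. None was higher in both. Their effects differed by 0.10 (Ctse, SE 0.37) and 0.07 (Chil1, SE 0.60) on the log2 scale. Wdfy1 (difference 3.19, adjusted p = 1.45e-05) and Dynlt1b (-4.49, adjusted p = 9.27e-07) were the 2 genes whose effects differed, in a test chosen after seeing the data (398 genes at an unadjusted p under 0.05). Lyz2 (1.73, adjusted p = 0.0809) and Arg1 (0.81, SE 0.57, adjusted p = 1) did not pass it. Across 13434 genes, which are not independent replicates, the fold changes correlated with Pearson's r of 0.017 and Spearman's rho of 0.11, and across 7775 genes with a mean of at least 10 CPM with r of 0.351 and rho of 0.22. The lower calls of the Il9r comparison were lower as a set in the Arg1 comparison (camera p = 1.52e-05, and 0.00308 with an estimated correlation), but without Ctse and Chil1 the p was 0.847.

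CD11c+ and CD11c- IM differed widely in WT cells of tumor-bearing lungs. Itgax, the gene of CD11c, was at 350 CPM in CD11c+ and 20 CPM in CD11c- libraries (log2 fold change 4.12, SE 0.31, adjusted p = 4.36e-07, n = 5 each). CD11c+ IM had more Dcstamp, a receptor needed for macrophage fusion (7.55), Perp (7.41), Plet1 (6.07), Klrb1b (6.22), Cacnb3 (4.70) and H2-M2 (5.62). They had more of the chemokines Ccl17 (6.56, SE 0.76, 48.2 against 0.548 CPM) and Ccl22 (5.95, SE 0.99, 95.2 against 1.55 CPM), which attract CCR4-bearing T cells. Ccl22 is also on the dendritic cell list, and Perp and Plet1 are on the alveolar macrophage list. Whether such values came from IM or from other cells in the CD11c+ sort cannot be told apart here. CD11c- IM had more Lyve1, a hyaluronan receptor (-4.54, SE 0.72, 1.38 against 31.3 CPM), the hemoglobin scavenger receptor Cd163 (-2.83, SE 0.70, 13.3 against 97.8 CPM), the endothelin receptor Ednrb (-3.24), Arhgef37 (-3.20), Fam20a (-3.19), Padi4 (-2.91) and Gja1 (-2.74). Arg1 was lower in CD11c+ IM (1480 against 4480 CPM, -1.69, SE 0.42, adjusted p = 0.0131). Of 13434 genes 1550 were called, 731 higher and 819 lower in CD11c+ IM, and 648 of them differed more than 2-fold. Ptprc was not called (-0.49, adjusted p = 0.247), but was without CD11c- WT library 2 of the IL9R chimeras (-0.76, adjusted p = 0.0481).

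MHC class II, lipid and cholesterol synthesis genes were higher in CD11c+ IM. Of 15 MHC class II genes 10 rose and 0 fell (adjusted over the list alone 11 and 1; camera adjusted p = 3.52e-07, and 0.147 with an estimated correlation), led by H2-DMb2 (2.85), H2-DMa (1.23), H2-DMb1 (1.46) and H2-Eb1, the class II beta chain (3430 against 848 CPM, 1.98, SE 0.35). Of 28 lipid genes 7 rose and 2 fell (adjusted over the list alone 7 and 2; 0.00287, and 0.29 with an estimated correlation), among them Gpnmb (3410 against 620 CPM, 2.46, SE 0.29), the fatty acid binding proteins Fabp5 (1.45) and Fabp4 (1.75) and the cholesterol exporter Abcg1 (0.98). Of 21 cholesterol synthesis genes 11 rose (adjusted over the list alone 13; 2.24e-07, and 0.147 with an estimated correlation), with Fdps (1.29), Dhcr7 (1.13), Fdft1 (1.03) and Cyp51 (1.09). Of 34 cell cycle genes 11 rose (adjusted over the list alone 22; 8.42e-10, and 0.402 with an estimated correlation), with the mitotic Birc5 (1.54), the replication helicase Mcm7 (1.20), H2afz (1.04) and Stmn1 (81.6 against 29.8 CPM). Of 21 alveolar macrophage markers 12 rose (adjusted over the list alone 13 and 1 lower; 4.16e-09, and 0.147 with an estimated correlation), with Cd9 (2.31), Atp6v0d2 (3.04), Ear2 (3.86) and Abcg1. Of 20 dendritic cell markers 6 rose (adjusted over the list alone 9; 4.44e-05, and 0.147 with an estimated correlation), with Fscn1 (4.43), Ccl22, the lymph node homing receptor Ccr7 (4.20, SE 0.76, 135 against 7.81 CPM) and Itgae (7.42). The alveolar and dendritic lists mark cells that a lung macrophage sort could also hold. Other cells in the sort and a state of the IM cannot be told apart by them. The same holds for the monocyte markers below. The matrix and protumor list did not pass (adjusted p = 0.17, and 0.712 with an estimated correlation): of 27 genes 7 rose and 4 fell (adjusted over the list alone 9 and 6), the proteases Mmp12 (3.11) and Ctsk (3.20) and the growth factor Pdgfa (1.85) being higher and Thbs1 lower (-1.81). With fry the adjusted p was 0.000798 for class II, alveolar and dendritic genes, 0.0034 for lipid, 0.00208 for cholesterol and 0.0293 for cell cycle genes.

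Interferon and hypoxia genes and monocyte markers were higher in CD11c- IM. Of 35 interferon genes 26 fell and 1 rose in CD11c+ against CD11c- IM (adjusted over the list alone 29 and 1; camera adjusted p = 8.63e-17, and 0.147 with an estimated correlation), with the RNA sensors Oas2 (-2.32) and Oas3 (-1.70) and Ifi204 (-1.49) lower and Cxcl9 higher (2.02). Of 27 glycolysis and hypoxia genes 6 fell (adjusted over the list alone 18; 4.11e-07, and 0.402 with an estimated correlation), with the hypoxia regulator Hif1a (-1.03), Pfkfb3 (-0.84), Bnip3 (-1.17) and Ero1l (-1.36). Of 14 classical monocyte markers 7 fell and 3 rose (adjusted over the list alone 9 and 3; 0.00509, and 0.147 with an estimated correlation), F13a1 (-1.91) and Ccr2 (-1.10) being lower and Mgst1 higher (1.52). Of 23 IM markers 7 fell (adjusted over the list alone 9, and 2 higher; 0.0274, and 0.657 with an estimated correlation), with Cbr2 (-2.46), Itgam (-1.19), Lyve1 and Folr2 (-1.99). With fry the adjusted p was 0.000798 for interferon genes and monocyte markers, 0.0211 for glycolysis and 0.0989 for IM markers. Of 24 arginine and polyamine genes 2 rose and 4 fell (adjusted over the list alone 3 and 6; 0.841): the arginine transporter Slc7a2 rose (2.17), while Arg1, the nitric oxide synthase Nos2 (-1.57) and the spermine oxidase Smox (-0.81) fell.

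The subset calls numbered 928 without CD11c- WT library 1 and 805 without CD11c+ WT library 2 of the IL9R chimeras. Some of the weaker calls rested on other libraries, and many on these 2. Without the first, Nos2 (adjusted p = 0.0617), Smox (0.185) and Itgae (0.057) lost their calls, and without the second Arg1 (0.064), Nos2 (0.0822), Smox (0.109), Cyp51 (0.0672) and Fdft1 (0.0733). Without CD11c+ WT library 1 of the IL9R chimeras Arg1 (0.0549), Cd163 (0.0723) and Mcm7 (0.0594) lost theirs, and without CD11c- WT library 2 Cd163 (0.107) and Cyp51 (0.0692). Voom did not call Lyve1 (adjusted p = 0.0614), Plet1 (0.127) or Perp (0.234), the highest adjusted p of each under any alternative. No called value of a named gene changed sign under any alternative.

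**Figure D4:**
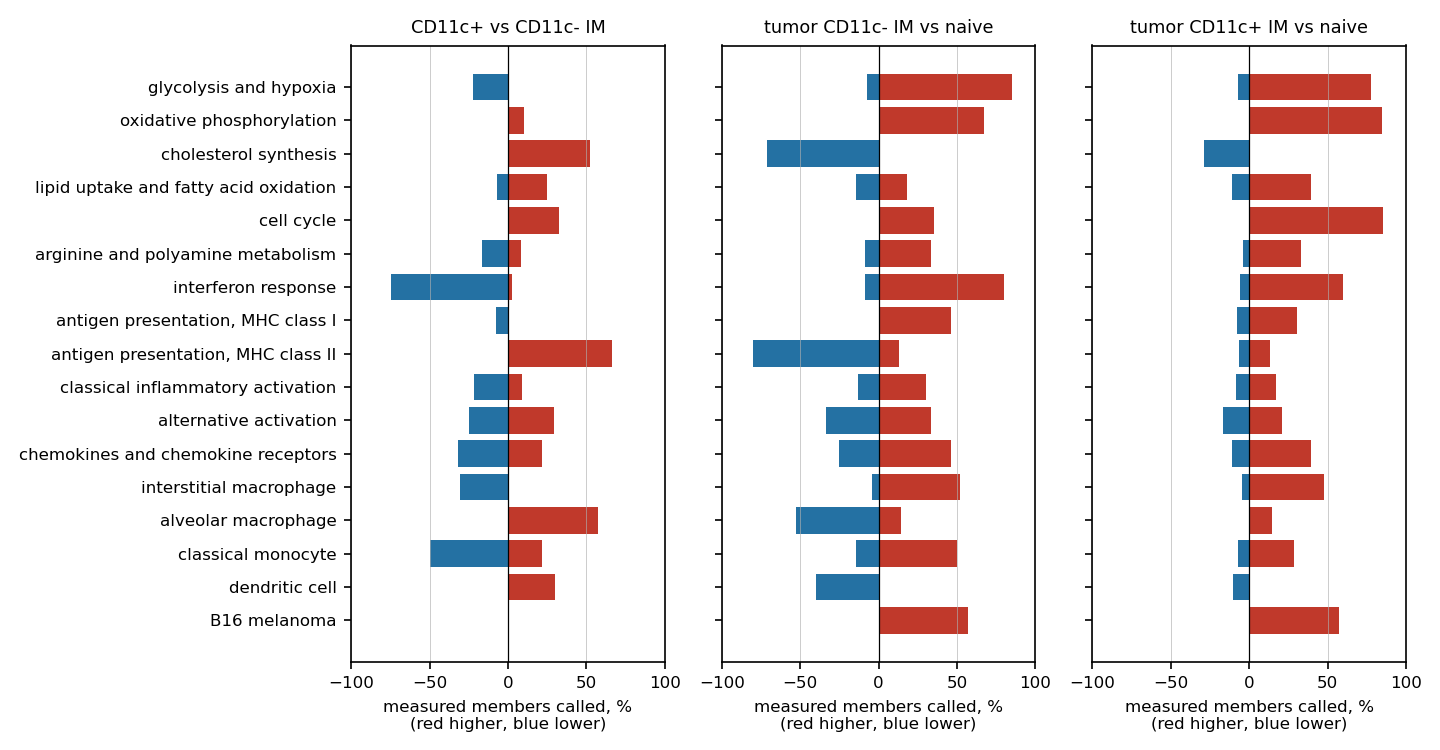
Bars give the percentage of measured members called higher (red) or lower (blue) for 17 gene lists in 3 comparisons: CD11c+ against CD11c- IM, CD11c- tumor IM against naive macrophages and CD11c+ tumor IM against naive macrophages, all in WT cells. Of 35 interferon genes 26 are lower in CD11c+ than in CD11c- IM, and 28 are higher in CD11c- tumor IM than in naive macrophages.

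Tumor IM were compared with naive total macrophages in WT cells, a comparison in which the tumor and the sorted population change together. Arg1 was at 4480 CPM in CD11c- tumor IM and 26.7 CPM in naive macrophages (log2 fold change 7.46, SE 0.52, adjusted p = 1.11e-06, n = 5 and 2). Melanoma transcripts were higher in the tumor sorts: Dct (9.43, 31.4 against 0.0442 CPM), Tyrp1 (6.88), Slc45a2 (at least 98.2-fold) and Ptgds (at least 83.1-fold), followed by Gja1 (7.58), the hypoxia-induced Ak4 (6.46) and Lipg (6.25). Lower were H2-M2 (-8.03), Dcstamp (-7.74), Ccl17 (-7.70, SE 0.67, 0.548 against 103 CPM), Mucl1 (-7.36), Ntn4 (-7.28), Klrb1b (-6.78), Hepacam2 (-6.63), Rnase2a (-6.49) and Itgax (-4.30, SE 0.27, 20 against 404 CPM). Of 13170 genes 3057 were called, 1713 higher and 1344 lower, and 2019 of them changed more than 2-fold. Only 2 naive WT libraries stand behind this: 1293 genes were called without that of the ARG1 chimeras, where Ntn4 had an adjusted p of 0.187 (0.0661 with DESeq2), and 1492 without that of the IL9R chimeras. Ptprc was not called (-0.74, adjusted p = 0.123), but was without CD11c- WT library 1 of the IL9R chimeras (-1.04, adjusted p = 0.0297).

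Hypoxia, interferon and arginine genes were higher in CD11c- tumor IM than in naive macrophages. Of 27 glycolysis and hypoxia genes 23 rose and 2 fell (adjusted over the list alone 25 and 2; camera adjusted p = 4.1e-16, and 0.138 with an estimated correlation), with Bnip3 (3.53), Ndrg1 (3.12) and the glycolytic enzymes Pgk1 (2.91) and Tpi1 (3.06, 1530 against 175 CPM). Of 35 interferon genes 28 rose and 3 fell (adjusted over the list alone 29 and 3; 9.2e-16, and 0.138 with an estimated correlation), with the antiviral Rsad2 (4.28, 247 against 13.2 CPM), Ifi204 (2.83), Ifit1 (3.57) and Oas3 (3.15). Of 24 arginine and polyamine genes 8 rose and 2 fell (adjusted over the list alone 8 and 2; 0.000945, and 0.182 with an estimated correlation), with Arg1, Nos2 (4.44) and Odc1, which makes putrescine from ornithine (1.77, 188 against 56.8 CPM), higher and Slc7a2 lower (-4.23). Of 23 IM markers 12 rose and 1 fell (adjusted over the list alone 15 and 2; 2.42e-05, and 0.138 with an estimated correlation), with Maf (4.19), Fcgr1 (3.18), Cbr2 (3.83) and Itgam (1.45). Of 14 classical monocyte markers 7 rose and 2 fell (adjusted over the list alone 7 and 2; 0.00463, and 0.138 with an estimated correlation), with Ly6c2 (4.56, 573 against 24.7 CPM), Ms4a4c (4.49), Vcan (5.58) and F13a1 (2.63). Of 14 B16 markers 8 rose (adjusted over the list alone 8; 2.46e-09, and 0.138 with an estimated correlation), with Dct, Tyrp1, Slc45a2 and Pmel (5.04). Of 15 MHC class II genes 12 fell and 2 rose (adjusted over the list alone 12 and 2; 0.000124, and 0.345 with an estimated correlation), with H2-Eb1 (-2.16), H2-Aa (-2.02, 1150 against 4670 CPM) and H2-DMb2 (-2.81) lower and the protease Lgmn higher (1.62). Of 21 cholesterol synthesis genes 15 fell (adjusted over the list alone 17; 3.78e-07, and 0.144 with an estimated correlation), with Cyp51 (-2.26), Hmgcs1 (-1.84) and Sc5d (-1.62). Of 20 dendritic cell markers 8 fell (adjusted over the list alone 8; 8.68e-05, and 0.138 with an estimated correlation), with Ccl22 (-6.07), Ccr7 (-4.19), Flt3 (-3.78) and Fscn1 (-3.59). With fry these 9 lists had adjusted p from 2.57e-05 to 0.00444.

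CD11c+ tumor IM were compared with the same 2 naive WT libraries. Arg1 was at 1480 against 26.7 CPM (log2 fold change 5.82, SE 0.48, adjusted p = 1.11e-05), while Itgax did not differ detectably (350 against 404 CPM, -0.17, SE 0.28, adjusted p = 0.722). Dct (8.78), Tyrp1 (5.90), Slc45a2 (at least 65.5-fold) and Ptgds (at least 89.2-fold) were higher, with Fcrl5 (5.66), Ak4 (5.52), Mpst (5.19) and the hypoxia sensor Egln3 (5.12, 34.3 against 0.945 CPM). Lower were the lectin receptors Cd209g (at least 160-fold) and Cd209f (-8.98), Firre (-8.99), Tppp (-8.26), Tgfbr3 (-6.08), Fam171a1 (-4.91), Rarb (-4.79) and Gbp2b (-4.12). Ptprc was lower (-1.21, SE 0.33, adjusted p = 0.016). In all 3055 genes were called, 1798 higher and 1257 lower, and 1898 changed more than 2-fold. Without the naive WT library of the ARG1 chimeras 1231 were called, and Mpst (adjusted p = 0.0774), Tgfbr3 (0.261), Fam171a1 (0.425, and 0.12 with voom), Rarb (0.123) and Ptprc (0.102) were not. Without that of the IL9R chimeras 1032 were called, and Mpst (0.0514), Tgfbr3 (0.0625), Gbp2b (0.122) and Ptprc (0.129) were not.

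Energy metabolism and cell division genes were higher in CD11c+ tumor IM than in naive macrophages. Of 40 oxidative phosphorylation genes 34 rose and 0 fell (adjusted over the list alone 36 and 0; camera adjusted p = 3.59e-15, and 0.398 with an estimated correlation), with Ndufa4 (1.92, 136 against 35.9 CPM), Atp5e (1.83), Atp5g1 (1.57) and Cox7b (1.45). Of 34 cell cycle genes 29 rose (adjusted over the list alone 31; 1.07e-13, and 0.345 with an estimated correlation), with Ccnb1 (4.42), Birc5 (3.53, 34.2 against 2.7 CPM), Ccnb2 (3.39) and Mcm5 (2.37). Of 27 glycolysis and hypoxia genes 21 rose and 2 fell (adjusted over the list alone 21 and 2; 9.87e-11, and 0.313 with an estimated correlation), with Tpi1 (2.81), Pgk1 (2.49), Ndrg1 (2.45) and Pgam1 (2.21). Of 35 interferon genes 21 rose and 2 fell (adjusted over the list alone 25 and 3; 1.71e-07, and 0.413 with an estimated correlation), with Oasl1 (3.26), Rsad2 (3.20), Ifit1 (2.41) and Ifit3 (2.29). Of 24 arginine and polyamine genes 8 rose and 1 fell (adjusted over the list alone 11 and 1; 0.000939, and 0.313 with an estimated correlation), with Arg1, the polyamine enzymes Paox (1.81) and Srm (102 against 38.9 CPM) and Odc1 (1.36). Of 28 lipid genes 11 rose and 3 fell (adjusted over the list alone 13 and 4; 0.0162, and 0.456 with an estimated correlation), with Fabp5 (2.85, 1310 against 186 CPM), Fabp4 (2.60), Gpnmb (2.04) and the lipase Lpl (1.55). Of 27 matrix and protumor genes 9 rose and 3 fell (adjusted over the list alone 10 and 3; 0.0144, and 0.433 with an estimated correlation), with Spp1, osteopontin (4.66, 7370 against 296 CPM), Timp1 (3.81), Thbs1 (2.30) and Ctsl (1.87). With fry these 7 lists had adjusted p from 0.000301 to 0.00715. Lpl (adjusted p = 0.0586) lost its call without the naive WT library of the ARG1 chimeras, and Lpl (0.0511) and Gpnmb (0.0773) without that of the IL9R chimeras.

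WT cells of the IL9R chimeras were compared with WT cells of the ARG1 chimeras, to see how far the chimera kinds differ in cells without either knockout. These WT cells developed beside Il9r KO or Arg1 CKO cells, and the WT donor of the ARG1 chimeras is not stated. Effects of the partner marrow, the donor and the set of mice cannot be told apart here. Higher in the IL9R chimeras were the cytokines Il6 (77.7 against 20.3 CPM, log2 fold change 1.94, SE 0.35, adjusted p = 0.0318) and Il1a (494 against 134 CPM, 1.87, SE 0.35, adjusted p = 0.0364), Trem1, which amplifies myeloid inflammation (1.37), and Tnfaip2 (1.27). Also higher were Dcstamp (3.28), Spata13 (1.84), Nr4a2 (1.66), Fbxo32 (1.48) and Ephx1 (1.41), and lower were Pex10 (-1.37), Coa4 (-1.11) and Rap2b (-0.88). Arg1 was not called (2520 against 3280 CPM, -0.51, adjusted p = 0.584), nor were Itgax (0.60, adjusted p = 0.271) and Ptprc (0.67, adjusted p = 0.218; 0.0494 without CD11c- WT library 2 of the IL9R chimeras). Of 40 oxidative phosphorylation genes 36 were negative, with 0 called over all genes and 20 adjusted over the list alone (camera adjusted p = 5e-10, and 0.851 with an estimated correlation). All 21 cholesterol synthesis genes were positive, with 1 called and 5 adjusted over the list alone (1.48e-05, and 0.851 with an estimated correlation). Of 23 genes of classical inflammatory activation 15 were positive, with 2 called and 7 adjusted over the list alone (0.0143, and 0.851 with an estimated correlation). With fry these 3 lists had an adjusted p of 0.26, 0.173 and 0.561. A block for the label number called more genes than the main fit and kept only part of its calls. In total the main fit called 36 genes, 31 higher and 5 lower. This count rested on single libraries: 0 were called without CD11c- WT library 1 of the IL9R chimeras or without CD11c- WT library 2 or 3 or CD11c+ WT library 2 of the ARG1 chimeras. It was 291 without CD11c- WT library 2, 6 without CD11c+ WT library 1 and 1 without CD11c+ WT library 2 of the IL9R chimeras, and 6 without CD11c- WT library 1 and 20 without CD11c+ WT library 1 or 3 of the ARG1 chimeras.

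In naive macrophages, with 1 library per group and no test, Ctse was lower in both knockouts: 11.7 against 66.3 CPM in the library labelled Il9r KO (log2 ratio -2.50) and 9.61 against 63.1 CPM in the CKO library (-2.71). Chil1 was at 17.4 against 31.2 CPM (-0.84) and 5.37 against 37 CPM (-2.77). Wdfy1 was higher in the library labelled Il9r KO (48.2 against 12.9 CPM, 1.90) and Dynlt1b lower (0.825 against 2.44 CPM, -1.51), and Fn3krp was at 6.07 against 0 CPM. Other genes called in tumor IM did not follow: Gdf3 was at 28.9 against 26.4 CPM (0.13) and Pydc3, lower in CD11c+ tumor IM, was at 7.7 against 1.08 CPM (2.77). In the CKO library Lyz2 was lower (10200 against 36400 CPM, -1.84) and Lyz1 higher (2630 against 408 CPM, 2.69), while Pwp2 was at 21.1 against 23 CPM (-0.13). Arg1 was at 285 against 15.8 CPM in the library labelled Il9r KO (4.17) and 7.37 against 37.5 CPM in the CKO library (-2.34).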

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

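The interaction tests were planned, and the tests of the 3 patterns weighed after them were chosen only after the results were seen. By camera with the preset correlation the difference between cells labelled Il9r KO and WT cells varied between CD11c+ and CD11c- IM in 4 lists, each with an adjusted p of 0.937 with an estimated correlation and 0.94 with fry. Of 40 oxidative phosphorylation genes 37 had a more negative difference in CD11c+ IM (median -0.32, camera adjusted p = 4.42e-05, and 0.937 with an estimated correlation). So had 26 of 28 chemokine and chemokine receptor genes (median -0.48, adjusted p = 0.0187, and 0.937 with an estimated correlation) and 19 of 23 IM markers (median -0.53, adjusted p = 0.00765, and 0.937). Of 21 cholesterol synthesis genes 16 had a more positive difference in CD11c+ IM (median 0.49, adjusted p = 0.0187, and 0.937 with an estimated correlation). CD11c+ library 3 labelled Il9r KO, 1 of 3 in its group, stood apart (principal component 3 at -65.31, B16 genes 0.127% of counts, Arg1 102 CPM). Without the IL9R chimera libraries numbered 3, left out only after the results were seen, none of the 4 lists passed: camera adjusted p was 0.0664 for oxidative phosphorylation, 0.33 for chemokines, 0.664 for IM markers and 0.0664 for cholesterol synthesis. The difference between Arg1 CKO and WT cells varied for the oxidative phosphorylation genes (37 of 40 more negative in CD11c+ IM, median -0.24, camera adjusted p = 0.0251, and 0.984 with an estimated correlation or 0.998 with fry). EdgeR called 0 single genes in either interaction (740 and 519 at an unadjusted p under 0.05, DESeq2 7 and 18, voom 0 and 0).

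Ctse and Chil1 were lower in the knockout libraries of both chimera kinds, by log2 fold changes of -2.85 to -3.01. A response to the tumor that needs Il9r or Arg1 is argued against by the naive libraries, except for Chil1 in the IL9R chimeras. The 4 naive log2 ratios averaged -2.20 (range -2.77 to -0.84, tumor mean -2.94), each from 1 library per group. For Chil1 in the IL9R chimeras the ratio was -0.84 (tumor -2.94), which leaves this open. Both genes lie within 20 Mb of Ptprc, the congenic marker on chromosome 1 (138062861 to 138175708), and a donor strain segment around it is a candidate explanation. Over the other 154 genes there the mean product of both comparisons' signed z values, each capped at 3 in size, was 0.487. It was at most 0.372 in 9559 windows of as many neighbouring genes elsewhere (percentile 100). These windows overlap and are not independent, so the percentile is not a p-value. Ppfia4 (0.55 and 0.73), Steap3 (-0.72 and -0.98), Ikbke (-0.65 and -0.80) and Ptprv (-5.57 and -6.49), chosen after their values were seen, moved the same way in both comparisons at an unadjusted p under 0.05, and 0 genes there moved apart. The WT donor of the ARG1 chimeras is not stated, and a biological effect of both genes on Ctse and Chil1 stays open as untested.

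Il9r reads appeared in all libraries labelled Il9r KO and in no WT library. Of the Arg1 CKO libraries, CD11c+ library 1 held 61 Il9r reads, and CD11c- library 3 and the naive library held 5 each. The source of these reads was not tested. An exchange of the WT and KO labels is argued against by the other genes called, since for 7 of 7 the libraries labelled WT lay closer to the WT libraries of the ARG1 chimeras, provided that both kinds share a WT donor strain, which is not stated. T cells in the sort are argued against as the source, since 6 of the 7 libraries held more Il9r reads (110 to 562) than reads of Cd3d, Cd3e and Cd3g together (0 to 80). The exception was CD11c+ library 3 labelled Il9r KO (83 against 455). B cells stay open as untested. Mast cells stay open too, as 0 of 5 mast cell and basophil markers were measured. Transcription from the targeted allele was not tested, as counts per gene do not show the exons.

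Lyz2 was lower and Lyz1 higher in the Arg1 CKO libraries. The sum of both genes was lower too (log2 fold change -1.35, exact permutation p = 0.005, the smallest possible, with each library counted as independent). This argues against reads moved to Lyz1 in counting as the source of the Lyz2 fall. Lyz2 makes up nearly all of the sum (11570 against 19.91 CPM of Lyz1 in CD11c- WT library 1 of the ARG1 chimeras). The sum therefore cannot tell whether the Lyz1 rise came from Lyz2 reads, or whether reads that match both genes were lost. An insertion in Lyz2 carried by the CKO donor is a candidate explanation, since Lyz2 was lower without tumor as well (naive log2 ratio -1.84, 1 library each), but the Cre driver is not stated. A segment of another strain on chromosome 10, where Lyz2 (117277331 to 117282321), Lyz1 (117287797 to 117292868) and Arg1 lie, cannot be told apart from this: its other genes ranked 3 of 20 chromosomes by mean absolute z, between the ranks set for and against it (2 and 10). This ranking left out the genes called for Arg1 and averaged each whole chromosome (0.758 for chromosome 10, range 0.704 to 0.761). A short segment could hardly show in it. Of the other genes called for Arg1, Pwp2 and Hal (93488768 to 93519304, called in CD11c+ IM) also lie on chromosome 10. Ctse, Chil1, Mapkbp1 and Ribc1 lie elsewhere. The naive log2 ratio of Pwp2 was -0.13 (tumor -1.44, 1 naive library each), and that of Hal is not given here. A biological effect of Arg1 on lysozyme stays open as untested.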

How the results depend on the processing

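Leaving out the IL9R chimera libraries numbered 3 and the block of paired libraries alone were chosen only after the results were seen; all other alternatives here were planned. The cause was not tested for any change below except where named. DESeq2 called more genes than edgeR for Il9r (29 in CD11c-, 34 in CD11c+, 53 averaged), Arg1 (10, 44 and 25), both interactions (7 and 18) and the WT cells of both chimera kinds (390). On simulated data, drawn with the dispersions that edgeR estimated, it made 22 to 50 false calls, against 2 to 11 for edgeR. Voom called 5 genes for Arg1 in CD11c- and 2 in CD11c+ IM. A block for the label number called 4 for Arg1 in CD11c- IM, 8 averaged and 157 between the WT cells of both chimera kinds (18 of the 36 shared), and changed no other count by more than 1.5 times. It called Il9r over both subsets (adjusted p = 0.0258). A block that ties only libraries paired by number called 5 for Il9r and 4 for Arg1 in CD11c- IM and 5 for Arg1 averaged, and did not call Il9r (0.323). Fits of only the groups contrasted, with fewer samples for the spread, called 0 for Il9r in either subset (550 and 307 genes at an unadjusted p under 0.05), 0 (258) and 2 for Arg1 and 2 between chimera kinds. With all 25 libraries 5661 genes were called between CD11c- tumor and naive macrophages. Without the IL9R chimera libraries numbered 3 the Il9r counts were 4 in CD11c-, 4 in CD11c+ and 7 averaged. The correlation of the genotype effects was 0.351 over genes of at least 10 CPM, against 0.017 over all. Of the list tests 89 passed with the preset correlation, 0 with an estimated one and 39 with fry. Leaving out 1 library at a time, counts ran from 3 to 51 (Il9r, CD11c-), 3 to 6 (CD11c+), 3 to 9 (averaged), 0 to 1 (Arg1, CD11c-), 1 to 5 (CD11c+), 3 to 8 (averaged), 0 to 12 and 0 to 1 (Il9r and Arg1 interactions), 805 to 1692 (IM subsets), 0 to 291 (chimera kinds), 1293 to 3165 (CD11c- against naive) and 1032 to 3101 (CD11c+ against naive), and the correlation from -0.076 to 0.07. An arm left with 1 library is assumed to vary like the others. DESeq2 size factors and no filter left all counts within 1.5 times. Of 325 called values of named genes 200 kept the call under every alternative, 125 lost it under at least 1 and 0 changed sign, and 4 of 40 uncalled ones were called under at least 1.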

Other observations

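Splits of the libraries and Arg1 against gene lists were planned tests. Chosen only after the results were seen were the splits that follow the numbers, the permutations that move libraries of one number together and the correlation without chromosome 1. Feedback genes of cytokine signaling differed between the IM subsets of WT cells. Of 20 genes of the IL-9 receptor and JAK-STAT list 2 rose and 5 fell in CD11c+ against CD11c- IM (adjusted over the list alone 3 and 10; camera adjusted p = 0.0274, and 0.636 with an estimated correlation): the STAT5-induced inhibitors Socs2 (log2 fold change 1.96, SE 0.23, 21.6 against 5.48 CPM) and Cish (1.48, SE 0.32, 43.8 against 15.5 CPM) were higher, and the IL-4 receptor Il4ra (-1.15, SE 0.19, 341 against 719 CPM) and Stat3 (-0.56, SE 0.14) lower. Against naive macrophages Socs2 (-3.40) and Cish (-2.63) were lower and Il4ra (1.48) and Bcl3 (1.35) higher in CD11c- tumor IM, with 5 of 19 genes higher and 3 lower (adjusted over the list alone 6 and 3; 0.67). Of 28 chemokine and receptor genes 6 rose and 9 fell in CD11c+ against CD11c- IM (adjusted over the list alone 9 and 12; adjusted p = 0.409), Ccl17, Ccl5 (2.07) and the interferon-induced Cxcl9 (2.02) being higher. Against naive macrophages the platelet factor Pf4 (3.69, 1470 against 120 CPM) was higher in CD11c- tumor IM and Ccl22 and Ccl17 lower, with 13 of 28 genes higher and 7 lower (adjusted over the list alone 14 and 9; 0.0522). Stat3 lost its call without CD11c- WT library 1 (adjusted p = 0.0763) or CD11c+ WT library 2 (0.0732) of the IL9R chimeras.

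Other matrix, activation and lymphocyte genes differed between tumor and naive macrophages. In CD11c- tumor IM Spp1 (4.22, 5500 against 296 CPM), Thbs1 (4.05, 2530 against 158 CPM) and Ctsl (2.67) were higher and the elastase Mmp12 lower (-3.81, 87.8 against 1240 CPM), with 7 of 27 matrix and protumor genes higher and 7 lower (adjusted over the list alone 9 and 7; camera adjusted p = 0.308). In CD11c+ tumor IM the alternative activation gene Retnla (-3.20, 43 against 398 CPM) and the transcription factor Irf4 (-2.35) were lower and Il10 (2.27) and Msr1 (1.13) higher, with 5 of 24 genes of that list higher and 4 lower (adjusted over the list alone 6 and 4; 0.967). T and NK cell markers were lower in CD11c+ tumor IM, 4 of 13 called (adjusted over the list alone 6, and 1 higher; 0.00372, and 0.313 with an estimated correlation), with Nkg7 (at least 35.9-fold), Cd3e (at least 7.26-fold), Cd2 (-3.32) and Prf1 (-7.37). Without the naive WT library of the ARG1 chimeras Irf4 (adjusted p = 0.0704), Nkg7 (0.196), Cd3e (0.385), Cd2 (0.402) and Prf1 (0.401) lost their calls, and Cd3e also without that of the IL9R chimeras (0.105) or without CD11c+ WT library 1 (0.0645) or 2 (0.0631) of the IL9R chimeras or 2 (0.0509) or 3 (0.0509) of the ARG1 chimeras.

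Between libraries of one group, Arg1 was compared with 15 gene lists as deviations from the group means over the 21 tumor libraries, with permutations within groups. Glycolysis and hypoxia genes were predicted to move with Arg1 and did not pass the correction (Pearson's r 0.57, permutation p = 0.0208, adjusted 0.0615; Spearman's rho 0.62, adjusted 0.0575; r 0.61 without the 2 libraries farthest from the median, 0.43 in the IL9R and 0.97 in the ARG1 chimeras). The prediction had named an adjusted p of 0.05 or more as evidence against it, which was wrong, since a p that misses the threshold does not show that values did not move together, so the question was left open after the result was seen. MHC class I genes correlated with Arg1 (r 0.79, adjusted permutation p = 0.00615; rho 0.88, adjusted 0.0084; r 0.79 without 2 libraries, 0.92 and 0.94 by chimera kind). Cholesterol synthesis genes (r -0.78, adjusted permutation p = 0.0212; rho -0.75; r -0.70 without 2), B16 markers (r -0.83, adjusted permutation p = 0.0217; rho -0.71; r -0.68 without 2) and cell cycle genes (r -0.51, adjusted permutation p = 0.0212; rho -0.67; r -0.43 without 2) had a negative correlation, with the same sign in both chimera kinds. These permutations treat the libraries as independent, although WT and knockout libraries of one number deviated alike in most groups, so their p are not exact. With libraries moved together where the numbers pair them, none of the 15 lists passed in 288 permutations: the adjusted p was 0.273 for MHC class I (unadjusted 0.0278), cholesterol synthesis (0.0556), cell cycle (0.059) and B16 genes (0.0729), where the smallest unadjusted p possible is 0.00347. With all libraries of one number moved together the adjusted p was 0.39 for each of these 4 lists (48 permutations, smallest unadjusted p possible 0.0208). With so few permutations no list could pass the correction over 15 lists by itself. A missed threshold here therefore does not decide the question.

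Only if each library counts as independent do the splits exclude chance for the number of genes called in 2 comparisons. In the averaged Arg1 comparison 5 were called (at most 2 in 99 other splits, 1 of 100 as large). Between the IM subsets 1550 were called (at most 455 in other splits, 1 of 60 as large). Of the 39 splits for Arg1 that part the 3 CD11c- pairs, the numbers of the CD11c+ libraries not being pairs, the highest other called 0 genes. Each subset was regrouped separately in these splits. CD11c- and CD11c+ WT libraries of one number deviated alike for numbers 1 and 2 (r 0.35 and 0.32), less for 3 (0.05). The CKO libraries did not (-0.14 and -0.18 for numbers 1 and 2). Splits that keep both subsets of a number together were not examined for Arg1, so chance is not excluded there if libraries are not independent. For the subsets 16 splits part all libraries of one number, with a highest other of 2, and are too few for a share under 0.05. Between WT cells of the chimera kinds 36 genes were called, with a highest other of 1 in 100 splits. The CD11c- and CD11c+ WT libraries of one number deviated alike (r 0.28 to 0.35 for 4 of 5 numbers, 0.05 for the other), and with both kept together 10 splits are left (highest other 1), too few for a share under 0.05. Chance cannot be excluded for the averaged Il9r comparison, where 5 of 100 splits called as many genes as the real 7. The highest other, 116, parts the libraries by number and not by genotype, which points to a structure of the samples that follows the numbers, and of the 16 splits that part all 4 pairs of WT and KO libraries the real one alone called any gene. For Arg1 in CD11c- IM (1 call, highest other 1, 2 of 10 splits) the splits are too few for a share under 0.05. A correlation of the genotype effects as high as 0.017 over all genes came up in 23 of 100 regroupings (highest other 0.109), so chance cannot be excluded, and without chromosome 1 genes it was 0.009. Over genes of at least 10 CPM 3 of 100 regroupings reached 0.351, with a highest other of 0.446, by Pearson's r, and 30 of 100 by Spearman's rho, so the result depends on the measure.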
